A study of Mus musculus with 8 samples.

How the data were processed

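Liver RNA of male mice in 2 genotype groups of 4 arrays was labelled with Cy3 and hybridised to a custom Agilent array, and the deposited scanner files give intensity values for each spot. All 8 arrays lay on 1 slide and share 1 scan date, so neither can act as a batch, and each column of the slide held 1 array of each genotype. Per the labels, RNA was isolated with TRIzol and selected for integrity, and mice are described both as fed until week 5 and as 5 weeks old. Sample numbers in the labels run through both genotypes and pair no samples. The labels describe samples of mice but do not say outright that each array is a separate animal, so p-values measure the spread between these samples.

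Per the file headers, the spots were quantified with Agilent Feature Extraction 11.5.1.1, while the submitters' processing notes name version 9.1. Per the file headers, the processed signal is an intensity after background subtraction and spatial detrending, with no normalization between arrays; mean and local background intensities are given beside it. The scanner files also carry the software's own marks for spots well above background, saturated or of outlying quality. The authors' value table holds linear intensities in 59448 rows, 1 per accession, with no stated scale; the sorted values of its 8 columns are the same, which is what quantile normalization gives, and each column has a median of 84.2. Its values run in the same order as the processed signal for at least 99.9% of neighbouring probes. The genome build in the file headers is mm9, but all probes are listed as unmapped and no coordinates are given here.

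The files hold 61473 spots other than controls, of 60273 probes. The accession of a probe was matched without its version to the RefSeq gene table of the GRCm38.p6 assembly, which was used only for names, chromosomes and gene order. This named 31064 probes, of 26698 genes, and left 29209 probes under their accession. Spots marked as outliers by the software were treated as missing (248 to 621 per array), none was saturated, and spots of 1 probe were averaged. The log2 processed signal was set relative to the 75th percentile of each array over all probes, since on average 77.6% of probes were well above background. Probes well above background on at least 4 of the 8 arrays were kept (46848), and each gene was represented by its probe with the highest mean signal. Of 43015 features, 33 had fewer than 2 values in a genotype, which left 42982, of them 23915 genes with a symbol and 19067 transcripts without one. Of the named genes, 5 had more than 1 kept probe, and in 1 of them, Orm3, these differed in sign. Where no array of a genotype measured a probe well above background, a fold is given as a lower bound, against the higher of the lowest signal well above background on each array and the probe's own signal.

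Genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, NB minus NN), with Benjamini-Hochberg adjustment and a threshold of 0.05. Gene lists were tested with camera at a preset correlation of 0.01, on the 32 lists with at least 3 measured members, with an estimated correlation and fry as alternatives. The lists were the chromosome 18 and the other immunity-related GTPases, guanylate-binding proteins, interferon-stimulated genes, antigen presentation, lists of lipid, cholesterol, glucose, bile acid, xenobiotic and mitochondrial metabolism, autophagy, stress, clock, acute phase, proliferation and sex-dependent genes, and markers of liver and other cell types. Enrichment on chromosome 18 was tested with a one-sided Fisher's exact test, and the densest window of 5.3 Mbp against 10000 random draws of as many tested genes.

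The named genes follow a rule that was set, with the lists, tests and alternatives, before the data were examined. It takes up to 15 called genes with a symbol in each direction and up to 15 called on chromosome 18, every measured chromosome 18 GTPase, the 4 members with the smallest p in the direction of each list past the threshold, the 5 features with the smallest p in a direction with under 5 calls, and the 2 members with the smallest p of 5 lists of lipid metabolism and autophagy. Of the genes under this rule, 1 is not reported here and was left out of the screen for single arrays far from their group. The transcripts AK089264 and XR_379331 and the genes Gm20556 and Lmo3 were named after their values or spot marks were seen. Alternatives covered normexp with an offset of 50, quantile, median and other percentile scaling, the authors' value table, filters on dim probes, the summary of probes, array weights, the variance model, slide row and column, each array left out with the probes as chosen on all 8, and an adjusted p of 0.1.

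The steps were tested on simulated data with the spread of the real arrays, in 42512 features with 50 changed at each size. At log2 changes of 0.5, 1, 2 and 3, 24%, 70%, 96% and 100% were called, with 7 false calls in all. For lists, the 1 shifted list and 0 of the other lists were called. Genes varied independently in this simulation, while the real cholesterol synthesis list had an estimated correlation of 0.937. The simulation therefore cannot show how the list test behaves where members vary together. Figures were drawn with matplotlib 3.10.9, and probe sequences were aligned with Biopython 1.88.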

Results

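RNA from the livers of male congenic mice was hybridised to 1-colour Agilent expression arrays, with 1 array per liver sample. The mice carried the genome of the New Zealand Obese (NZO) strain, a polygenic mouse model of obesity and fatty liver, and differed by genotype in a segment of 5.3 Mbp on chromosome 18. The labels name the genotypes Ltg/NZO.5.3N/N (NN below, n = 4 arrays) and Ltg/NZO.5.3N/B (NB below, n = 4 arrays), where the crossing partner of the NZO strain was C57BL/6J. All mice ate a diet with 45% fat until week 5. The 75th percentile of the processed signal lay between 445 and 584.4 intensity units, and between 74.9% and 80.1% of probes stood well above background on each array. The number of arrays limits the precision of every value given here. Pearson correlations between arrays, taken across genes, ranged from 0.989 to 0.996, with a median of 0.993 both within and between genotypes, so the genotypes did not separate on expression as a whole.

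The comparison between the genotypes asked which liver transcripts differ between mice described as differing in the chromosome 18 segment, a segment studied for its link to liver triglycerides. Few features were called. Of 42982 features tested with limma, 3 differed at an adjusted p under 0.05, and all 3 were higher in NB. The largest change was in F830016B08Rik, a chromosome 18 gene of the interferon-inducible immunity-related GTPases, which act in cell-autonomous defence against intracellular pathogens. Its signal was 12.7-fold higher in NB (95% confidence interval 8.79 to 18.3; log2 fold change 3.66, SE 0.233, adjusted p = 0.00225). The mean log2 signal relative to the array percentile was −1.68 ± 0.20 (SD, n = 4) in NB and −5.34 ± 0.51 (SD, n = 4) in NN, where only 2 of the 4 arrays measured it well above background.

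Vmn1r65, a vomeronasal receptor gene on chromosome 7, was 3.19-fold higher in NB (log2 fold change 1.67, SE 0.137, adjusted p = 0.0129), at −1.96 ± 0.18 against −3.63 ± 0.24 (SD, n = 4 each). The transcript AK089264, which the reference table does not pair with a gene and which is named here because it was 1 of only 3 calls, was 4.05-fold higher in NB (log2 fold change 2.02, SE 0.0929, adjusted p = 0.000292). All 4 NB arrays lay above all 4 NN arrays for each of the 3. No feature was lower in NB at this threshold. At an unadjusted p under 0.05, 726 features differed, which is fewer than the number that chance alone gives for a list of this length; over the alternatives this count ranged from 553 to 1454 for the whole array. The call of Vmn1r65 was lost when any of 6 of the 8 arrays was left out, with adjusted p between 0.0579 and 0.101, while its log2 fold change stayed between 1.59 and 1.78. With normexp background correction, which adds an offset of 50, the log2 fold changes were smaller. They were 1.55 for F830016B08Rik (adjusted p = 3.62e-05), 0.91 for Vmn1r65 (adjusted p = 0.00167) and 0.69 for AK089264, which lost its call (adjusted p = 0.0747).

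**Figure D1:**
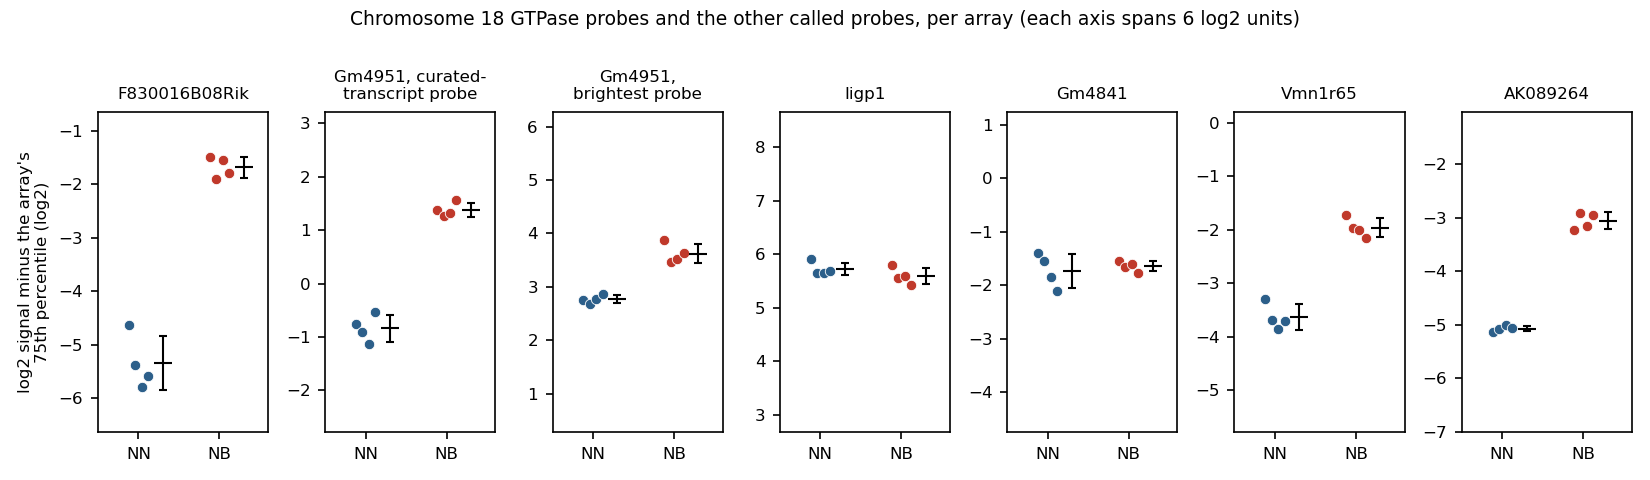
Log2 signal minus the 75th percentile of the array, for each of 4 NN (blue) and 4 NB (red) arrays; bars are the mean and SD, and each panel has its own level but the same span. F830016B08Rik, both Gm4951 probes, Vmn1r65 and AK089264 were higher on all NB arrays than on any NN array, while the values of Iigp1 and Gm4841 overlapped.

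Among the 4 measured immunity-related GTPases of the chromosome 18 cluster, only F830016B08Rik passed the test over all features, and 2 passed when adjusted over the list alone. The second was Gm4951, another GTPase of the cluster. Its brightest probe was 1.81-fold higher in NB (log2 fold change 0.85, SE 0.103, adjusted p = 0.166), and the values of the genotypes did not overlap. A second probe of Gm4951, designed to its curated RefSeq transcript, was 4.63-fold higher in NB (log2 fold change 2.21, SE 0.133) and passed when every probe was tested separately (adjusted p = 0.0015). Put in place of the brightest probe it gave an adjusted p of 0.00145, which rests on the same values and was added after the data were seen. With eBayes trend and robust settings Gm4951 was called from its brightest probe (adjusted p = 0.0301). Iigp1, the best studied member of the family, had a log2 fold change of −0.13 (SE 0.102), and Gm4841 had 0.08 (SE 0.151). Intervals of 95% for these genes allowed at most a 1.29-fold lower level of Iigp1 and a 1.35-fold higher level of Gm4841 in NB. As a list, the 4 GTPases were higher in NB than other genes (camera with a preset correlation, adjusted p = 1.97e-07), with a median log2 fold change of 0.47 and adjusted p = 0.274 with an estimated correlation. With the filter on all 8 arrays, which removes F830016B08Rik, the median was 0.0848 (adjusted p = 0.0145). This was also the only list that fry called (adjusted p = 0.0241).

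Other interferon-responsive families did not pass the test. The 9 measured immunity-related GTPases outside chromosome 18 had a median log2 fold change of 0.14 (adjusted p = 0.144), and the 26 measured interferon-stimulated genes had one of 0.04 (adjusted p = 0.0598). The 9 guanylate-binding proteins had a median of −0.10 (adjusted p = 0.688), and the 17 antigen presentation genes had one of 0.00424 (adjusted p = 0.211). None of the members of these 4 lists was called over all features or adjusted over the list alone. The interferon-stimulated list passed with normexp (adjusted p = 0.00201), without a filter (0.0477), with the mean of a gene's probes (0.0472) and with eBayes trend and robust settings (0.042), and without NN 1, NB 3, NB 5 or NN 6 (0.0113 to 0.0305), while adjusted p rose to 0.838 without NB 2. Antigen presentation passed with normexp (adjusted p = 0.0403) and the authors' value table (adjusted p = 0.0494).

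The position of differing genes on chromosome 18 was examined next, with gene order taken from the GRCm38.p6 table. Of the 2 called genes with a position, 1 lay on chromosome 18, against 598 of 23915 tested genes, which is 2.5% (one-sided Fisher's exact test, p = 0.0494). With a single called gene there, the densest window of 5.3 Mbp on the chromosome held 1 gene. When p-values were adjusted over the 598 chromosome 18 genes alone, a family chosen after the data were seen, 5 genes passed, and a single window of 5.3 Mbp held all 5. They were F830016B08Rik (adjusted p = 6.25e-05), Gm4951 (adjusted p = 0.00578), the sulfate transporter gene Slc26a2 (adjusted p = 0.0263), the macrophage growth factor receptor gene Csf1r (adjusted p = 0.0424) and the pseudogene BC023105 (adjusted p = 0.0463). Slc26a2 was 1.66-fold higher in NB (log2 fold change 0.73, SE 0.112), Csf1r was 1.37-fold higher (log2 fold change 0.46, SE 0.0784), and BC023105 was 1.59-fold lower (log2 fold change −0.67, SE 0.120). Over all features these 4 other genes had adjusted p-values of 0.166, 0.708, 1 and 1.

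Along the chromosome, Gm4951, Gm4841, F830016B08Rik, Iigp1 and BC023105 stood next to each other among the tested genes. After 16 further genes came Pdgfrb, the platelet-derived growth factor receptor beta of stellate cells, then Csf1r, and after 1 more gene Slc26a2. Pdgfrb had a log2 fold change of 0.36 (SE 0.118, adjusted p = 1) with its brightest probe and 0.08 with the other. At an unadjusted p under 0.01, a threshold added after the data were seen, 7 of 48 genes with a position lay on chromosome 18, or 14.6% (one-sided Fisher's exact test, p = 0.000178). The densest window there held 6 genes, a number that random draws of as many genes reached anywhere in the genome with a share of 2e-04. Sequence variants under the probes of chromosome 18 genes were not tested, so a difference in signal there need not be one in transcript level.

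**Figure D2:**
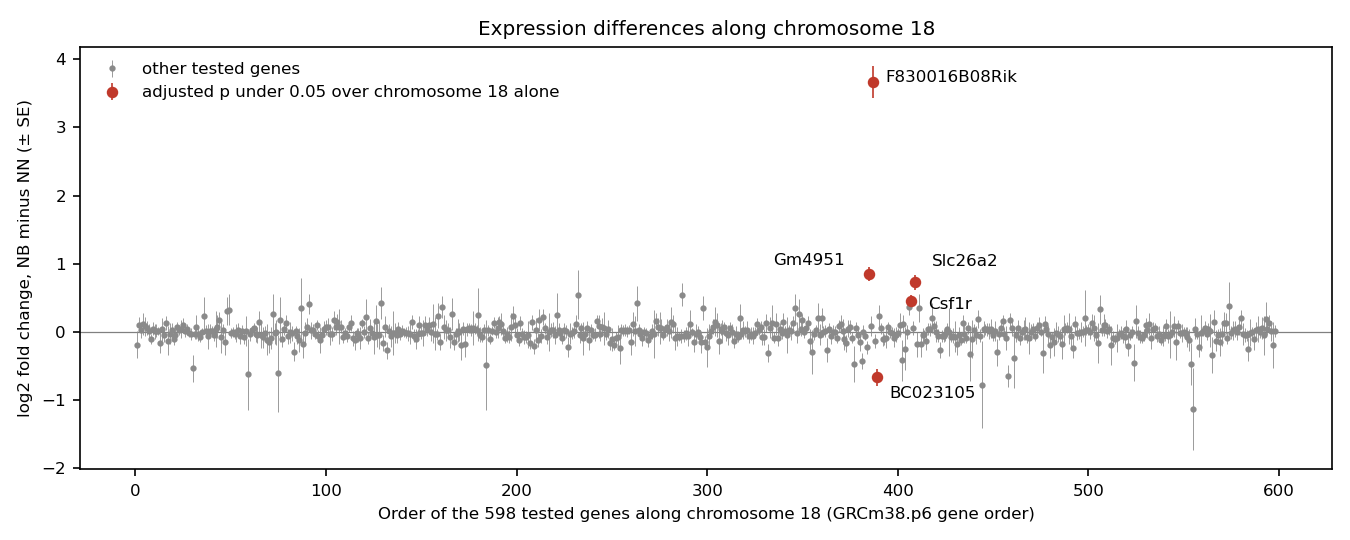
Log2 fold change, NB minus NN, with its SE for each of the 598 tested genes in their order along chromosome 18; red points have an adjusted p under 0.05 over chromosome 18 alone. The 5 red genes lie close together, with F830016B08Rik at 3.66 and the others between −0.67 and 0.85.

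Inflammation and macrophage lists were higher in NB. Of the 19 measured acute phase genes, which hepatocytes express in inflammation, 17 had a positive log2 fold change, and the list as a whole was higher in NB than other genes (median log2 fold change 0.25, camera adjusted p = 4.11e-06; adjusted p = 0.547 with an estimated correlation). The lipocalin gene Lcn2, whose product binds bacterial siderophores, had a log2 fold change of 0.79 (SE 0.409), the serum amyloid gene Saa3 1.22 (SE 0.687), and the orosomucoid genes Orm1 and Orm3 0.44 (SE 0.247) and 0.43 (SE 0.251). The other 2 probes of Orm3 gave −0.24 and −0.0025. Of 11 Kupffer cell markers, 10 were positive, with a median of 0.17 (adjusted p = 6.48e-05; adjusted p = 0.547 with an estimated correlation), among them Clec4f at 0.18 (SE 0.0906) and Adgre1, which encodes F4/80, at 0.22 (SE 0.113). Of 11 markers of recruited macrophages and monocytes, 9 were positive, with a median of 0.09 (adjusted p = 0.000173; adjusted p = 0.400 with an estimated correlation). Csf1r, also among the chromosome 18 genes above, was the member called when adjusted over the list alone. It was followed by Spp1 at 0.47 (SE 0.218), Ly6c2 at 0.34 (SE 0.193) and Cd68 at 0.23 (SE 0.149). The values of Spp1, Ly6c2 and Cd68 overlapped between the genotypes, and Spp1 is also on the cholangiocyte list, which did not pass. None of the acute phase, Kupffer cell or macrophage genes was called over all features. The scores of the acute phase and Kupffer cell lists were both negative on NN 1, NN 4 and NB 2 and positive on the other 5 arrays. With 1 array left out, the median of the recruited macrophage list lay between 0.0231 and 0.198.

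Stellate cell and matrix markers were also higher as a list, with 11 of 13 positive and a median of 0.09 (adjusted p = 0.00607; adjusted p = 0.547 with an estimated correlation), and Pdgfrb led its members. The cholesterol synthesis list had 20 of 21 members positive and a median of 0.17 (adjusted p = 0.00768; adjusted p = 0.721 with an estimated correlation). Its members varied widely between arrays of the same genotype. Msmo1 had a log2 fold change of 0.48 (SE 0.469) and Nsdhl 0.36 (SE 0.396). Of 21 proliferation genes 16 were positive, with a median of 0.14 (adjusted p = 0.0386; adjusted p = 0.667 with an estimated correlation), and Top2a had 0.45 (SE 0.279). No member of these 3 lists was called, over all features or adjusted over the list alone. The cholesterol synthesis and proliferation lists each lost their call when any of 5 arrays was left out (adjusted p up to 0.977), and the stellate cell and matrix list without NN 4 (adjusted p = 0.177) or NB 5 (adjusted p = 0.693).

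The lists of oxidative phosphorylation, lipogenesis, xenobiotic metabolism and glucose metabolism were lower in NB. All but 1 of the 27 oxidative phosphorylation genes had a negative log2 fold change, and the list was lower than other genes by a small amount (median −0.10, camera adjusted p = 6.67e-11; adjusted p = 0.513 with an estimated correlation). Ndufb8 of complex I was at −0.19 (SE 0.0748), Cox5a of complex IV at −0.16 (SE 0.0707) and Sdhb of complex II at −0.21 (SE 0.0918). Of 24 lipogenesis genes 22 were negative, with a median of −0.18 (adjusted p = 5.28e-06; adjusted p = 0.547 with an estimated correlation). Scd1, the stearoyl-CoA desaturase, was at −0.69 (SE 0.270), the malic enzyme gene Me1 at −0.55 (SE 0.199), the pyruvate kinase gene Pklr at −0.44 (SE 0.212) and Acacb at −0.34 (SE 0.219). Of 20 xenobiotic metabolism genes 14 were negative (median −0.17, adjusted p = 0.00647; adjusted p = 0.400 with an estimated correlation), including Cyp3a11 at −0.24 (SE 0.107) and Gstm2 at −0.30 (SE 0.129). Of 20 glucose metabolism genes 15 were negative (median −0.13, adjusted p = 0.00821; adjusted p = 0.547 with an estimated correlation), with the glucose-6-phosphatase gene G6pc at −0.73 (SE 0.336). No member of these 4 lists was called over all features or adjusted over the list alone. The glucose metabolism list lost its call without NB 2, NB 3 or NN 7 (adjusted p from 0.169 to 0.297), and the xenobiotic metabolism list without NB 3 (adjusted p = 0.088).

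**Figure D3:**
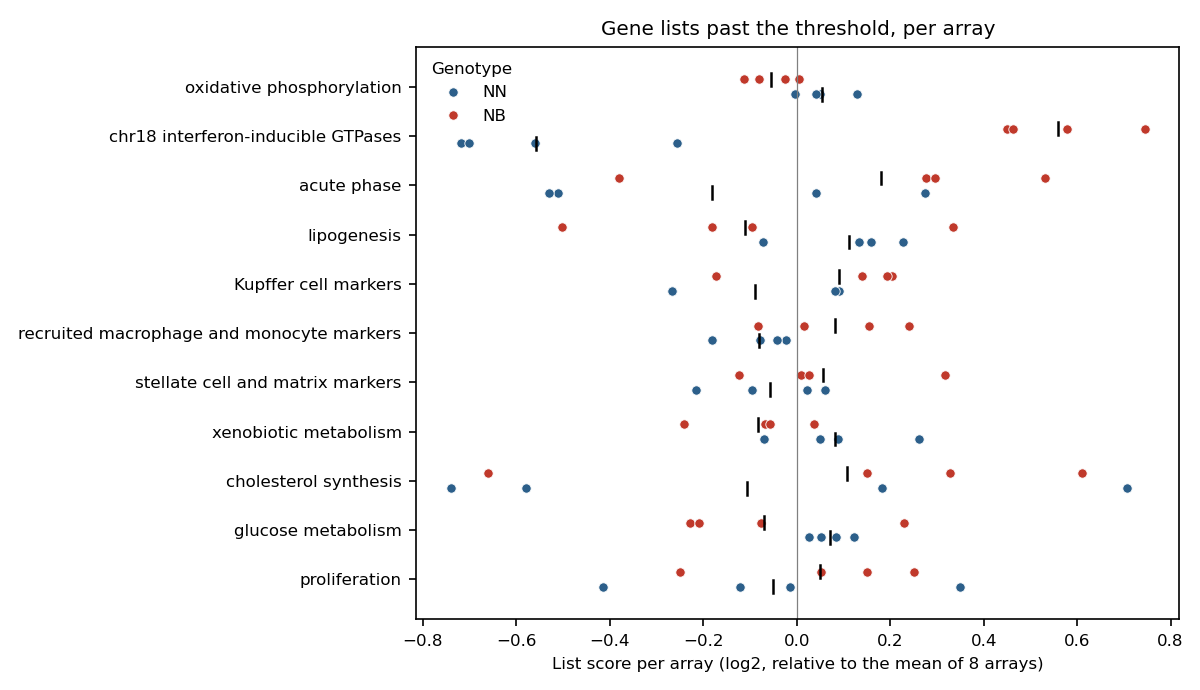
Score of each of the 11 lists past the threshold on each array, as the mean over members of the log2 value minus the member's mean over 8 arrays; points are arrays of the NN (blue) and NB (red) genotypes and black marks are genotype means. Only the chromosome 18 GTPase list, with scores from 0.45 to 0.74 in NB and from −0.72 to −0.26 in NN, had no overlap between genotypes.

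Of the 32 lists tested, 11 passed with the preset correlation, 7 higher and 4 lower in NB, but 0 passed with an estimated correlation and 1 by fry. The lists of fatty acid oxidation and ketogenesis (26 genes, median −0.04, adjusted p = 0.286), lipid droplets and lipolysis (18 genes, median −0.02, adjusted p = 0.986), and autophagy and lysosome (35 genes, median −0.01, adjusted p = 0.707) did not pass, although fatty acid oxidation and ketogenesis passed, lower in NB, without NN 4 (adjusted p = 0.0215). In these lists the pantetheinase gene Vnn1 had a log2 fold change of 0.23 (SE 0.169), the lipid droplet genes Plin1 and Plin5 0.24 (SE 0.123) and −0.26 (SE 0.149), the autophagy kinase gene Ulk1 −0.21 (SE 0.133) and the lysosomal lipase gene Lipa −0.11 (SE 0.0989).

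Among features that did not pass, the 5 with the smallest p in each direction were the genes Gm4951, Slc26a2, BC023105, Klrb1a and Mir7118 and 5 transcripts without a gene name. AK034086 was well above background on the 4 NB arrays and on 0 NN arrays, at least 2.50-fold higher in NB (adjusted p = 0.166), and XR_373418 had the same pattern, at least 1.58-fold higher (adjusted p = 0.670). Klrb1a, a receptor gene of natural killer cells, had a log2 fold change of 0.59 (SE 0.0994, adjusted p = 1). In the other direction stood XR_378327 at −0.89 (SE 0.125, adjusted p = 0.451), ENSMUST00000136484 at −0.43 (SE 0.0726), XM_003945749 at −0.63 (SE 0.119) and the microRNA gene Mir7118 at −0.75 (SE 0.143), the last 3 with an adjusted p of 1. With normexp background correction several of these were much closer to 0. The log2 fold changes were 0.30 for AK034086, 0.12 for XR_373418, 0.05 for Klrb1a, −0.22 for XR_378327, −0.13 for ENSMUST00000136484 and −0.19 for Mir7118. The folds and bounds given for them hold only without this setting. It adds an offset of 50, which by itself draws the log2 fold changes of dim probes toward 0, and the share of the offset was not tested.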

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

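Of 198 sets of 4 arrays of 1 genotype that were examined (the named genes, the list scores and the array measures), 12 held 1 array far from the other 3. Chance gives about 5% of sets, so this number is close to chance, and the sets are not independent. Single cases below may therefore be chance. The tests below of list members on chromosome 18, of the probes of Gm4951 and of the surroundings of Vmn1r65, and the comparisons within slide columns and slide rows, were chosen only after the results were seen.

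Array NB 8 stood apart as a whole, with a mean correlation of 0.990 to the other arrays, where the other NB arrays had 0.993. Array NB 2 was low for acute phase and Kupffer cell genes, with Orm1 at 5.89 (others 6.68 to 6.81), Orm3 at 6.35 (others 7.11 to 7.23), Folr2 at 2.13 (others 2.39 to 2.43) and a Kupffer cell score of −0.173 (others 0.139 to 0.203), all as log2 values. Array NN 7 had a high Saa3 signal of 2.89, against 0.236 to 0.588 on the other NN arrays. Array NB 3 was low for Cox5a (6.13), Ccna2 (−3.69) and the transcript AK034086 (−4.78), and NB 5 was high for Atp5c1 (4.85). Array NN 1 was high for Iigp1 (5.90, others 5.65 to 5.68) and low for the hepatocyte marker score (−0.0247).

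The 3 features called between the genotypes were weighed against a chance division of the arrays. Only 1 of the 35 splits of the 8 arrays into 4 and 4, the real one, gave 3 calls, and the highest of the others was 0. This is the most that 35 splits can show, and it does not exclude chance for the count. The calls held with slide column and slide row in the model. Within the 4 slide columns, each with 1 array per genotype, the log2 difference of F830016B08Rik ranged from 3.15 to 4.25, that of AK089264 from 1.86 to 2.18 and that of Vmn1r65 from 1.55 to 1.85. Among the splits that keep slide columns whole, 7785, 2144 and 1428 features had an unadjusted p under 0.05. The real split had 726, the lowest of all 35, and the other splits that mix columns had from 728 to 4679. Variation between arrays apart from the genotype widens the spread within groups, so the low count does not show that few features differ.

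The 11 lists past the threshold do not carry the same weight. Splits of the arrays gave between 2 and 11 lists, and 2 of the 35, the real one and 1 other, gave 11, so chance cannot be excluded for the number of lists. Nor do small p-values of single lists exclude it. The smallest unadjusted camera p was 2.08e-12 in the real split, for oxidative phosphorylation, and several other splits gave smaller ones, down to 1.44e-24. Array NB 8 is not the whole source, since 9 of the 11 lists remained past the threshold in the same direction without NB 8. Of the macrophage and matrix lists, 2 have a member on chromosome 18. Without these list members both of the 2 remained with the preset correlation (camera adjusted p = 0.0114 for recruited macrophages and 0.0402 for stellate cells and matrix). With them, adjusted p was 0.000173 and 0.00607. The pass in this test thus does not rest on Csf1r and Pdgfrb alone. Since the same test passes lists in other splits, how far these 2 genes carry the lists stays open. Within the 4 slide columns the difference in score had the direction of the list in all 4 for oxidative phosphorylation, the GTPases, acute phase and Kupffer cells, in 2 for cholesterol synthesis and in 3 for the others, and in only 1 of the 2 slide rows for lipogenesis, cholesterol synthesis and proliferation. What stays open is variation between samples in inflammation and feeding state that fell unevenly on the genotypes by chance, and an effect of the genotype on it.

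For Gm4951, the smaller fold change of its brighter probe may come from cross-hybridization with the abundant Iigp1 transcript. In the best local alignment 85.1% of the bases of that probe were identical to the Iigp1 probe, against 22.2% for the probe of the curated transcript, and the log2 fold change of Iigp1 itself was −0.13 (SE 0.102). A sequence variant under either probe, or under that of F830016B08Rik, was not tested. Neither was a match of the Gm4951 probes to parts of the Iigp1 transcript outside its probe. An effect of the genotype on the transcript stays open for Gm4951 as for F830016B08Rik. The single probe of F830016B08Rik shares no stretch of 20 bases with any other probe of the array, which does not test matches to other transcripts.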

How the results depend on the processing

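The count of 3 calls, all higher in NB, stayed between 2 and 4 under all alternatives over the whole array, and F830016B08Rik was called in each of 23 alternatives that tested it, with log2 fold changes from 1.55 (normexp) to 3.90. The filter on all 8 arrays removed F830016B08Rik, which leaves no call on chromosome 18 (Fisher's exact p = 1). The same test of chromosome 18 missed its threshold with the authors' value table (p = 0.0731), without a filter (p = 0.0503) and, added after the data were seen, with outlier-marked spots kept (p = 0.0728). Also chosen later, adjusting over chromosome 18 alone gave 5 genes, and an unadjusted p of 0.01 put 6 genes in the densest window. The densest window held 2 called genes, F830016B08Rik and Gm4951, with normexp and with the mean of a gene's probes. The same held with each probe tested separately and with eBayes trend and robust settings. Random draws of as many genes reached 2 with shares from 0.0167 to 0.0191. Such draws do not allow for related genes that lie close together, as in this GTPase cluster. Of the 11 lists, 0 remained with an estimated correlation and 1, the chromosome 18 GTPases, with fry; the other alternatives gave 9 to 14 lists. These 2 tests leave the median log2 fold changes as they were, at 0.47 for the chromosome 18 GTPases, 0.25 for acute phase, 0.168 for Kupffer cells, 0.0948 for recruited macrophages, 0.0868 for stellate cells and matrix, 0.174 for cholesterol synthesis, 0.138 for proliferation, −0.0973 for oxidative phosphorylation, −0.182 for lipogenesis, −0.172 for xenobiotic metabolism and −0.127 for glucose metabolism. The proliferation list also lost its call with quantile normalization (median 0.141), median centring (0.145), the authors' value table (0.146) and array weights (0.144). Other medians moved while the calls stayed, to −0.0548 and −0.0577 for oxidative phosphorylation and −0.0799 and −0.0800 for glucose metabolism with quantile normalization and the authors' value table, 0.0678 for proliferation with normexp, 0.15 and 0.189 for recruited macrophages and for stellate cells and matrix with array weights, 0.161 for recruited macrophages without a filter, and 0.809 for the chromosome 18 GTPases with the mean of a gene's probes. With 1 array left out at a time, calls were lost by the lists of cholesterol synthesis (5 of 8 sets, medians from 0.00524 to 0.482), proliferation (5 of 8, 0.0128 to 0.278), glucose metabolism (3 of 8, −0.204 to −0.0444), stellate cells and matrix (2 of 8, 0.000422 to 0.194) and xenobiotic metabolism (1 of 8, −0.184 to −0.105). The lists that kept their calls in all 8 sets had medians from 0.132 to 0.363 (acute phase), 0.130 to 0.230 (Kupffer cells), 0.0231 to 0.198 (recruited macrophages), 0.412 to 0.523 (chromosome 18 GTPases), −0.345 to −0.0996 (lipogenesis) and −0.129 to −0.0776 (oxidative phosphorylation). Vmn1r65 lost its call in 6 of 8 such sets, Idi1 ranged from −0.0243 to 0.551 and Gm4841 from −0.0440 to 0.195, both changing sign. With each probe tested separately, Orm3 had −0.24. The causes were not tested, other than the filter. No scaling moved the median log2 fold change of all features by over 0.1.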

Other observations

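Gm20556, a long non-coding RNA gene on chromosome 15 chosen after its values were seen, left the comparison because the software marked its spot as an outlier on all 4 NB arrays and on 0 NN arrays. With these spots kept, the processed signal was 319, 283.7, 187.2 and 158.8 on the NB arrays and 35.8, 54.0, 33.1 and 21.8 on the NN arrays, a 6.42-fold higher level in NB (log2 fold change 2.68, limma adjusted p = 0.0429), and the authors' value table gave 2.69 (adjusted p = 0.0247). In the opposite direction, the software marked Lmo3 and the transcript XR_379331 on all 4 NN arrays and on 0 NB arrays, and with these spots kept their log2 fold changes were −0.48 and −0.24.

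Acute phase, Kupffer cell, cholesterol synthesis and stress response genes varied between arrays within each genotype. The acute phase score was −0.511 and −0.53 on NN 1 and NN 4, 0.042 and 0.274 on NN 6 and NN 7, −0.38 on NB 2, and 0.532, 0.277 and 0.296 on NB 3, NB 5 and NB 8. The Kupffer cell score was −0.266, −0.267 and −0.173 on NN 1, NN 4 and NB 2, 0.0909 and 0.0812 on NN 6 and NN 7, and 0.203, 0.193 and 0.139 on NB 3, NB 5 and NB 8. The cholesterol synthesis score was −0.579, −0.74 and −0.66 on NN 1, NN 4 and NB 2 and between 0.151 and 0.708 on the other arrays, and the score of the endoplasmic reticulum stress and amino acid response list was −0.294, −0.333 and −0.293 on these 3 and between 0.0339 and 0.315 on the others. Markers of other cell types did not pass the test between the genotypes, with adjusted p of 0.0733 for hepatocytes, 0.0835 for T and NK cells, 0.349 for neutrophils, 0.654 for erythroid cells, 0.688 for adipocytes, 0.762 for cholangiocytes, 0.975 for sinusoidal endothelium, 0.975 for B and plasma cells and 0.346 for exocrine pancreas. Neither did bile acid synthesis (0.129), sex-dependent genes (0.144), stress response (0.168), lipoprotein secretion (0.26) and the circadian clock (0.584). Some of these lists passed under an alternative, namely stress response with normexp (0.0168), T and NK cells with the mean of a gene's probes (0.0489), and, with 1 array left out, stress response without NB 2, NN 6 or NN 7 (0.000175 to 0.00899), hepatocytes without NN 1, NB 5 or NB 8 (0.00488 to 0.0311), T and NK cells without NN 4 or NB 5 (0.0219 and 0.0288), and bile acid synthesis, sex-dependent genes and neutrophils without NN 7 (0.0162, 0.0434 and 0.0436).

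Around F830016B08Rik, 8 of 55 other tested genes within a window of 5.3 Mbp had an unadjusted p under 0.05, or 14.5% (95% exact binomial interval 6.5% to 26.7%), against 1.32% elsewhere (one-sided Fisher's exact test, p = 6.96e-07). The window was centred on a gene called in the same data, and neighbouring genes may vary together, so this p-value and interval only describe it. A hypothesis, formed after the call of Vmn1r65 was seen, was that the mice also differ in a second segment of C57BL/6J origin around this chromosome 7 gene, which could raise it along with its neighbours. In a window of the same length around Vmn1r65, 2 of 110 genes, or 1.82% (0.221% to 6.41%), had an unadjusted p under 0.05, against 1.34% elsewhere (one-sided Fisher's exact test, p = 0.437). This share and its interval lie below the lower bound of the chromosome 18 window. The surroundings of Vmn1r65 thus showed no excess like that on chromosome 18. This cannot decide the question, since another segment need not hold as many differing genes. A second segment, a variant in the gene itself or an effect of the chromosome 18 genotype remains open. The probe of Vmn1r65 shares no stretch of 20 bases with any other probe of the array, which does not test matches to other transcripts.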
